A study of Mus musculus with 6 samples.

How the data were processed

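RNA of whole testes from postnatal day 5 was enriched for polyadenylated messages with oligo dT beads, per the labels' protocols. The authors deposited 1 table of expected counts for 57170 gene identifiers in 6 libraries, in which the values need not be whole. Per the submitters' processing notes the reads were handled with fastp, STAR and RSEM and the build mm39; the roles of these tools, their versions, the gene annotation and whether strand was used in counting are not given in the sources used here. RSEM divides reads that match several genes among them, so genes with near-identical copies are uncertain. Of the identifiers, 444 have no Ensembl form. Symbols came from an annotation of GRCm38 (GENCODE M21), which matched 51742 identifiers (90.5%) holding 99.2% of the counts. Because that assembly is not the one of the counts, no coordinates are given, and it was used only for names, neighbours, chromosomes, biotypes and transcript properties. The oxidative phosphorylation gene Atp5pb, the Sertoli gene Fshr, the germ cell gene Tdrd9 and the erythroid gene Ahsp were not analysed here.

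Libraries were grouped by their titles, which match the genotype labels: 2 WT and 4 sKO. The series' design text speaks of 3 replicates per group, which differs from these labels, and the labels were used. Replicates were compared before averaging. The chi-square per gene between libraries of 1 group ran from 4.07 (sKO-3 and sKO-4) to 24.8 (sKO-1 and sKO-4), where sampling noise alone gives about 1. No libraries were therefore pooled, and each counted as 1 replicate. The value was 6.85 for sKO-1 and sKO-2, but 20.3 to 24.8 between either of these and sKO-3 or sKO-4. The 4 sKO libraries thus fell into pairs, and the main test, which has no covariate, treats them as independent. The totals of 17.99 to 18.4 M (mega) counts leave counting error small beside the spread between libraries for all but the lowest genes. Several of the genes with the largest falls were that low in sKO.

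Expected counts were rounded to whole numbers. Genes were filtered with edgeR's filterByExpr (minimum count 10, genotype as group), which left 17707 genes, and library sizes were scaled by TMM. The main comparison was edgeR's quasi-likelihood test (glmQLFit and glmQLFTest, edgeR 4.0.16 in R 4.3.3), two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05, with all 6 libraries and no covariate. SE of a log2 fold change is its size divided by the root of the F statistic. CPM are counts scaled to a common total over TMM-scaled library sizes, and log2 CPM carry a prior count of 2. For 23 gene lists, written from textbook knowledge before the data were examined, camera (limma 3.58.1) was run on log2 CPM with a preset correlation between genes of 0.01 and with Benjamini-Hochberg adjustment over the lists. Beside it stand the members past the edgeR test over all genes and over the list alone. All 13 list calls of camera were lost when the correlation was estimated from the libraries, and 8 of them were lost with fry.

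Genes were named by a rule set before the data were examined. It takes Mdm2, Trp53 and Mdm4, and the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold whose 4 sKO values lie on 1 side of both WT values and whose mean is at least 1 CPM. It also takes in each list up to 4 members with the smallest adjusted p under 0.05 or, with none, the 2 most abundant. Genes with no symbol, with Gm and a number, or ending in Rik or -ps were counted and not named by the rule. Other names were chosen after their values were seen: Gtsf1, Pld6, Brdt, Id4, Etv5, Nanos2, Ddx4, Sox9, the p53 targets beyond Cgref1, and those in the closing section. List members under the count filter were not tested. 1 gene that the rule takes is not reported here.

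Alternatives set before the data were examined were DESeq2 1.42.0 with its own filtering in place of the count filter, limma-voom, size factors of the RLE and upper-quartile kind, library sizes set to the summed Sertoli cell genes, no count filter, at least 1 CPM in 4 libraries, leaving out each library, a log2 fold change of at least 1, and the replicate number as a block. For lists they were an estimated correlation, fry, RLE and Sertoli library sizes, left-out libraries and the block, and for the pan-germ-cell list an exact permutation test of its share of counts. Where 1 WT library was left, it was assumed to vary like the sKO libraries. Added after seeing the data were a term for the 2 library subsets, each subset alone, the 4 libraries numbered 1 and 2 without the block, DESeq2 on the genes that passed the count filter, and counts that were not rounded. The order of libraries in the deposited table was not used for grouping. Transcript sequences were compared with BLAST 2.17.0.

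The steps were tested on simulated data: counts of 17707 genes drawn for the sKO against WT comparison from the real means, library sizes and dispersions, with 200 genes changed. The edgeR test called 5 of 67 genes changed 1.5-fold, 27 of 67 changed 2-fold and 42 of 66 changed 4-fold, each in the right direction, and 10.8% of its calls were unchanged genes. DESeq2 called 160 genes of which 37.5% were unchanged, and limma-voom 81 of which 9.88% were unchanged. Camera called 0 of 23 lists in these counts, and only the pan-germ-cell list once that list was halved in sKO. Each gene was drawn on its own, so these counts held neither correlation within lists nor the library subsets, and they did not test whether the preset correlation suits the real lists.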

Results

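Whole testes of mice at postnatal day 5 were profiled by bulk sequencing of polyadenylated RNA. The 6 libraries fall into 2 groups by their titles and genotype labels. The WT group holds 2 wild-type libraries, named WT-1 and WT-2. The sKO group holds 4 libraries, named sKO-1 to sKO-4, from mice that lacked Mdm2 conditionally in germ cells before meiosis. Mdm2 encodes the ubiquitin ligase that holds the tumour suppressor p53 (gene Trp53) at low levels. At this age the seminiferous cords contain Sertoli cells, the somatic nurse cells, and spermatogonia, the mitotic germ cells. The labels do not say that each library came from a separate animal, so p-values measure the spread between these libraries. The summed expected counts, in units of M (mega), were 18.3 M in WT-1, 18.2 M in WT-2, 18.4 M in sKO-1, 18.3 M in sKO-2, 17.99 M in sKO-3 and 18.1 M in sKO-4. Between 24858 and 26377 genes had a count in a library, and 17707 genes entered the comparison of sKO with WT.

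The comparison asked first whether the targeted gene was lower in the libraries labelled sKO. Mdm2 (ENSMUSG00000020184) was at 67.2 CPM (counts scaled to a common library size) in WT-1 and 75.9 in WT-2. It was at 37.6 in sKO-1, 47.3 in sKO-2, 41.8 in sKO-3 and 45.1 in sKO-4, below both WT libraries in each case. The group means were 71.6 ± 6.19 CPM (SD, n = 2) in WT and 43.0 ± 4.24 CPM (SD, n = 4) in sKO, a log2 fold change of −0.74 (SE 0.11, edgeR adjusted p = 0.0241). Germ cell transcripts were lower in the same libraries, and counts of a whole gene can include exons that a deletion spares. The fall of Mdm2 therefore does not by itself measure the deletion. The Mdm2 log2 fold change was −0.67 within the first and −0.81 within the second of the pair of library subsets described with the principal components. Its call ended without WT-1 (adjusted p = 0.168), WT-2 (0.107), sKO-2 (0.0550), sKO-3 (0.0764) or sKO-4 (0.0509), and held without sKO-1 (0.0490). Transcripts of Trp53 and of Mdm4, the p53-binding paralog of Mdm2, did not pass the test. Their log2 fold changes were 0.18 (SE 0.19, adjusted p = 0.788) and 0.04 (SE 0.13, adjusted p = 0.955).

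Transcripts of germ cells were lower in sKO testes. Dazl, an RNA-binding protein of germ cells, fell from 186 ± 44.3 CPM (SD, n = 2) to 36.9 ± 9.02 (SD, n = 4), a log2 fold change of −2.34 (SE 0.22, adjusted p = 0.00929). Of the 26 measured genes expressed across germ cells, 23 were lower and 0 higher, with a median log2 fold change of −2.28. Stra8, which retinoic acid induces as spermatogonia differentiate, fell from 27.0 ± 4.44 CPM to 1.85 ± 0.986. Zbtb16, a transcriptional repressor of undifferentiated spermatogonia, fell from 49.3 ± 20.6 CPM to 10.3 ± 2.47, and Lin28a, an RNA-binding protein of the same cells, from 31.8 ± 6.76 to 6.34 ± 1.84.

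Among the pan-germ-cell genes, Rbm44 (log2 fold change −2.71), the co-chaperone Fkbp6 (−2.06) and Rnf17 (−2.29), a Tudor-domain protein, had adjusted p of 0.00929, 0.00929 and 0.0110. The 3 members that did not pass were Gtsf1 (−2.32), Pld6 (−0.54) and Brdt (−0.28). Adjusted over the list alone, 25 members were lower, and also with the library subset as a term. The list held 0.106 ± 0.0257% of the normalised counts in WT and 0.0229 ± 0.00607% in sKO. Its share was lower in all 4 sKO libraries than in both WT libraries, which gives the smallest two-sided p that an exact permutation test over the 15 assignments allows, 0.0667. The camera test gave an adjusted p of 1.59e-31 with its preset correlation and an adjusted p = 0.230 with an estimated correlation. Fry, which asks whether a list's genes move 1 way on balance, gave an adjusted p of 0.0115. The median difference was −2.46 among WT-1, sKO-1 and sKO-2 and −2.04 among WT-2, sKO-3 and sKO-4.

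Of 23 measured genes of differentiating spermatogonia and early meiosis, 14 were lower and 0 higher, or 21 lower adjusted over the list alone (median log2 fold change −2.20, or −2.46 and −1.84 within the subsets). Scml2, a chromatin regulator, fell from 95.9 ± 10.7 to 26.1 ± 3.84 CPM. Stra8 (−3.87, SE 0.37), the transcription factor Sohlh1 (−3.07, SE 0.31) and the cohesin subunit Stag3 (−2.16, SE 0.23) fell with adjusted p of 0.00929, 0.00970 and 0.0110. Of 20 measured genes of undifferentiated spermatogonia, 8 were lower and 0 higher, or 13 lower adjusted over the list alone (median −0.95, or −1.15 and −0.97 within the subsets). They included Sox3 (−3.95, SE 0.43), Lin28a (−2.32, SE 0.26), Rhox10 (−3.25, SE 0.41) and Zbtb16 (−2.25, SE 0.28), with adjusted p of 0.0110, 0.0110, 0.0138 and 0.0138. Id4 (−0.74), Etv5 (−0.07) and Nanos2 (−0.87) did not pass. Members ran from −3.95 to 0.13, and the list held 0.0778 ± 0.00429% of the normalised counts in WT and 0.0587 ± 0.00333% in sKO. Which cells of the testis supply each member was not tested. The medians of the germ cell lists therefore do not rank the loss of 1 germ cell type against another. Camera gave adjusted p of 1.90e-23 for the differentiating list and 1.74e-11 for the undifferentiated list, and an adjusted p = 0.230 for each with an estimated correlation. Fry gave adjusted p of 0.0115 for the differentiating list and 0.0258 for the undifferentiated list. With the library subset as a term, 19 genes of the differentiating and 13 of the undifferentiated list were lower and 0 higher. Without WT-1, no member of these 3 germ cell lists passed the threshold, while the medians were −1.99 for the pan-germ-cell list, −1.86 for the differentiating list and −0.95 for the undifferentiated list.

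**Figure D1:**
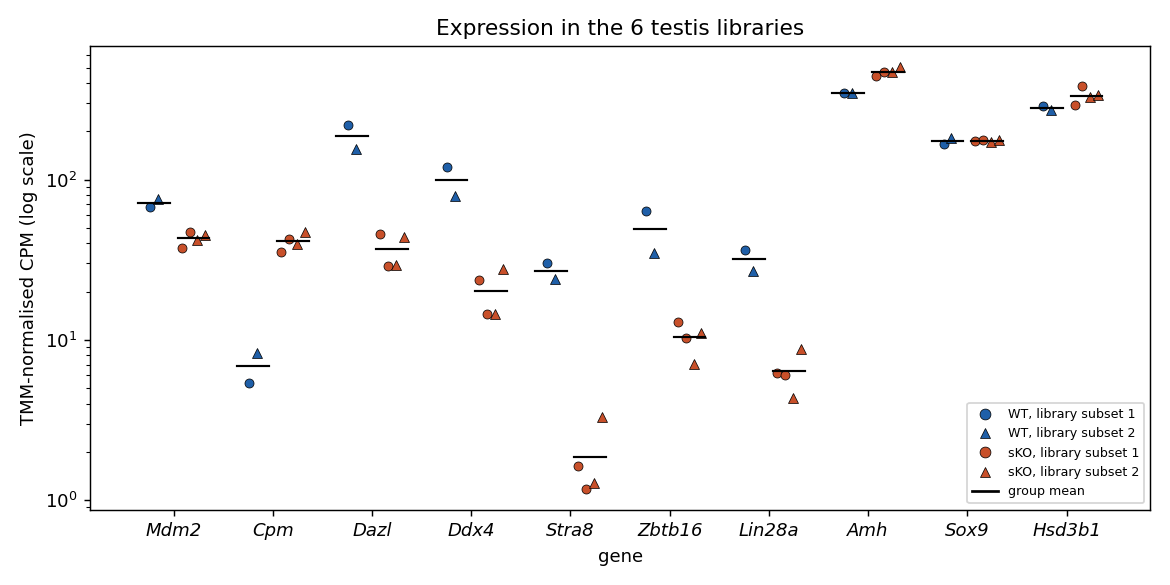
TMM-normalised CPM on a log axis (y) of 10 genes (x) in each library, with WT in blue, sKO in orange, circles and triangles for the 2 library subsets and a bar for each group mean. Dazl, Ddx4, Stra8, Zbtb16 and Lin28a lie lower in all 4 sKO libraries than in both WT libraries, Cpm and Amh lie higher, and Sox9 is at 174 CPM in WT and 175 in sKO.

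Across all genes tested, 22 were higher and 408 were lower in sKO (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). At 4081 of the 17707 genes the groups did not overlap. Chance gives 13.3% of genes if the 6 libraries are exchangeable. The library subsets described with the principal components put that in doubt, so the share is a rough guide. Among genes named by the rule, the largest falls were those of Sox3, Stra8, Dmrtb1 (−3.77, SE 0.70), Fam90a1b (−3.47), the retinoic acid binding protein Crabp1 (−3.35, SE 0.38), Rhox10, Sohlh1, Piwil1 (−3.04), Ccdc172 (−2.92) and Tex16 (−2.89). Dmrtb1 and Piwil1, which act in spermatogonia and in the piRNA pathway, were at 5.96 and 3.13 CPM in WT and at 0.434 and 0.374 CPM in sKO. Rhox10, Fam90a1b and Sox3 were at 0.290, 0.357 and 0.732 CPM in sKO. At such levels counting error is not small, so the sizes of these falls are uncertain. Of the lower genes, 64 have no usable symbol and were not named by the rule.

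Among genes named by the rule, the largest rise was that of Cpm, a membrane carboxypeptidase gene next to Mdm2 on chromosome 10 in the GRCm38 annotation, from 6.84 ± 2.04 CPM (SD, n = 2) to 41.2 ± 5.06 (SD, n = 4). Its log2 fold change was 2.59 (SE 0.22, adjusted p = 0.00929). Pnmt, the enzyme that makes adrenaline from noradrenaline, rose by 2.34 (SE 0.23, adjusted p = 0.00970), from 6.48 ± 0.00782 to 32.9 ± 6.59 CPM. Cbln1, a secreted cerebellin, rose by 1.46 (SE 0.10, adjusted p = 0.00530), from 116 ± 11.9 to 319 ± 10.6 CPM. The others were Vstm2a (1.38), the noncoding RNA Snhg18 (0.72), the tight junction protein Cldn1 (0.68), Svep1 (0.68), Abca8b (0.62), the desmosomal protein Dsp (0.60) and Map7d3 (0.58), with adjusted p from 0.0351 to 0.0482. Without WT-1 the adjusted p of the Cpm log2 fold change was 0.0896, that of Pnmt 0.121 and that of Cbln1 0.0352. Vstm2a, Cldn1, Svep1, Abca8b, Dsp and Map7d3 also lost their calls when library size was set to the Sertoli cell genes. Of the higher genes, 4 have no usable symbol and were not named by the rule. Whether counting used strand is not given in the sources used here, and Cpm and Mdm2 lie on opposite strands.

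The first principal component, with 38.1% of the variance, separated WT-1, sKO-1 and sKO-2 (subset 1) from WT-2, sKO-3 and sKO-4 (subset 2), and the second, with 32.6%, separated sKO from WT. The labels name no batch, and each subset holds 1 WT and 2 sKO libraries. Leaving out WT-1 or WT-2 therefore leaves WT in 1 subset, and such a fit mixes the subset difference with genotype. With a term for the subset, chosen after seeing the data, 880 genes were higher and 1531 lower in sKO. These included all 22 and all 408 of the genes above. Because the term was picked from the same libraries, the p-values of this fit may be too small for their nominal level. Within subset 1 alone 312 genes were higher and 1028 lower, and within subset 2 alone 126 and 276, with 1 WT library assumed to vary like the sKO libraries. Of the 35 named genes past the threshold, 34 lost their call without WT-1, 15 without WT-2, 14 without sKO-1, 16 without sKO-2, 17 without sKO-3 and 13 without sKO-4. Over all genes, leaving out single libraries gave 1 higher and 1 lower gene without WT-1, 7 and 195 without WT-2, 6 and 181 without sKO-1, 5 and 104 without sKO-2, 6 and 148 without sKO-3, and 7 and 221 without sKO-4. In the fit without WT-1 the 1 higher gene was Cbln1 and the 1 lower gene Gm12191, named here after their values were seen.

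**Figure D2:**
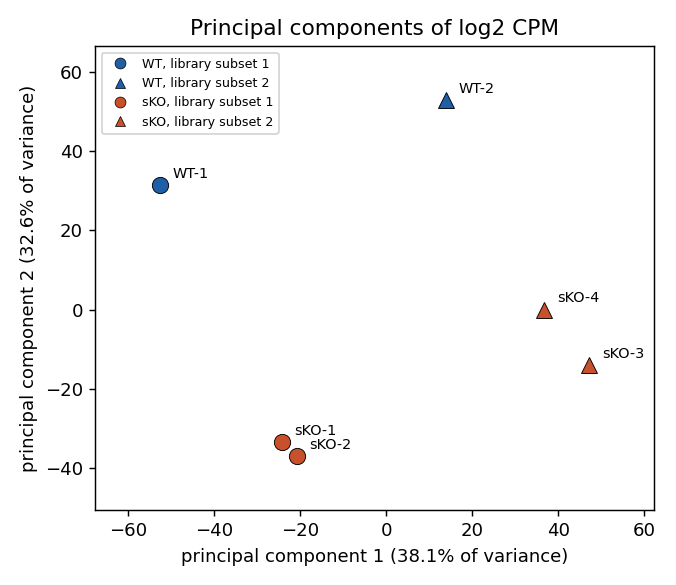
The first (x, 38.1% of the variance) and second (y, 32.6%) principal components of log2 CPM over 17707 genes, 1 point per library, with WT in blue, sKO in orange, circles for subset 1 and triangles for subset 2. The x axis separates the 2 library subsets and the y axis separates the 4 sKO libraries from the 2 WT libraries.

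Few targets of p53 passed the main edgeR test in whole testis. In the simulated counts this test called 5 of 67 genes changed 1.5-fold, so changes of that size could be missed. Mdm2 was targeted in germ cells, while the libraries hold RNA of all cells of the testis. A change limited to germ cells could be diluted, or hidden by the fall of germ cell transcripts. The values below therefore do not measure the p53 response of germ cells. Of 47 measured targets, 0 were higher and 1 was lower, also when adjusted over the list alone. The lower gene was Cgref1, a regulator of cell growth, at 6.96 ± 0.516 CPM (SD, n = 2) in WT and 2.45 ± 0.696 (SD, n = 4) in sKO (log2 fold change −1.51, SE 0.29, adjusted p = 0.0430). Without any 1 of the 6 libraries in turn, the adjusted p of the Cgref1 log2 fold change was 0.337 (WT-1), 0.130 (WT-2), 0.0989 (sKO-1), 0.109 (sKO-2), 0.0955 (sKO-3) and 0.0569 (sKO-4). The list had a median log2 fold change of 0.18 (0.25 and 0.11 within the subsets) and a camera adjusted p of 0.0336, with an adjusted p = 0.348 with an estimated correlation and an adjusted p = 0.162 with fry. Fry for changes in either direction gave an adjusted p of 5.38e-04, against 1.70e-04 for the Sertoli, 1.97e-04 for the retinoic acid and 0.00113 for the myoid list. A small value was thus not particular to the p53 list. The p53 list held 0.151 ± 2.48e-04% of the normalised counts in WT and 0.166 ± 0.00435% in sKO. An exact permutation test of that share gave p = 0.0667, the smallest it allows. This test was set beforehand only for the pan-germ-cell list. It also gave 0.0667 for the undifferentiated, differentiating, epididymis and rete, proliferation and niche factor lists. With library size set to the Sertoli cell genes the median of the p53 list was 0.03. The medians of the Sertoli (0.15), stromal (0.17) and endothelial (0.22) lists were similar in size, and germ cell transcripts were lower in the same libraries. The call of the p53 target genes was also lost without WT-1 (0.0512), without WT-2 (0.116) and without sKO-1 (0.0657). With the library subset as a term, 9 targets were higher, among them Ephx1 (0.65, adjusted p = 0.00402), Plk2 (0.43, 0.0106), Eda2r (0.88, 0.0118), Phlda3 (0.43, 0.0255) and Ccng1 (0.30, 0.0267), and 4 were lower, among them Pmaip1 (−0.86, 0.0379); these were named after their values were seen. Of the other classical targets, Cdkn1a was at 0.64 (adjusted p = 0.239 without the term and 0.0543 with it) and Bax at −0.16 (0.677 and 0.205).

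Of 26 measured genes of the apoptosis machinery, 0 passed the test, over all genes or over the list alone (median 0.08), and with the subset term 1 was higher and 2 were lower. The most abundant were the survival factor Mcl1 (0.11, SE 0.21) and cytochrome c, Cycs (0.19, SE 0.14), and camera gave an adjusted p of 0.589. A change limited to germ cells could be missed here too. At an unadjusted p under 0.05 in edgeR 2317 of 17707 genes passed. DESeq2 passed 2211 of 17691 with the same count filter, chosen after seeing the data, and 2234 of 32531 without it. Of 27 measured proliferation genes, 2 were lower and 0 higher, or 6 lower adjusted over the list alone, with a median of −0.22 (−0.30 and −0.17 within the subsets, −0.13 without WT-1 and −0.32 without WT-2). The mitotic cyclin Ccnb1 fell from 128 ± 0.950 to 89.0 ± 5.85 CPM (−0.53, SE 0.09, adjusted p = 0.0276) and the replicative helicase subunit Mcm7 from 200 ± 21.9 to 146 ± 4.61 (−0.45, SE 0.09, adjusted p = 0.0473). With the library subset as a term, 12 proliferation genes were lower and 0 higher. Without WT-1, WT-2, sKO-1, sKO-2 or sKO-3 the number lower was 0, and without sKO-4 it was 1. Camera gave an adjusted p of 1.37e-05, and an adjusted p = 0.347 with an estimated correlation. The share of germ cell transcripts was lower in the same 4 libraries. Leaving out WT-1, WT-2, sKO-1, sKO-2 or sKO-3 ended the call of the Ccnb1 log2 fold change (adjusted p 0.232, 0.0956, 0.0698, 0.0893 and 0.0918). Leaving out any library, RLE factors (0.0532), upper-quartile factors (0.0662) and limma-voom (0.0524) ended that of the Mcm7 log2 fold change (0.369 for WT-1, 0.0523 for WT-2, 0.113 for sKO-1, 0.113 for sKO-2, 0.153 for sKO-3 and 0.116 for sKO-4).

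**Figure D3:**
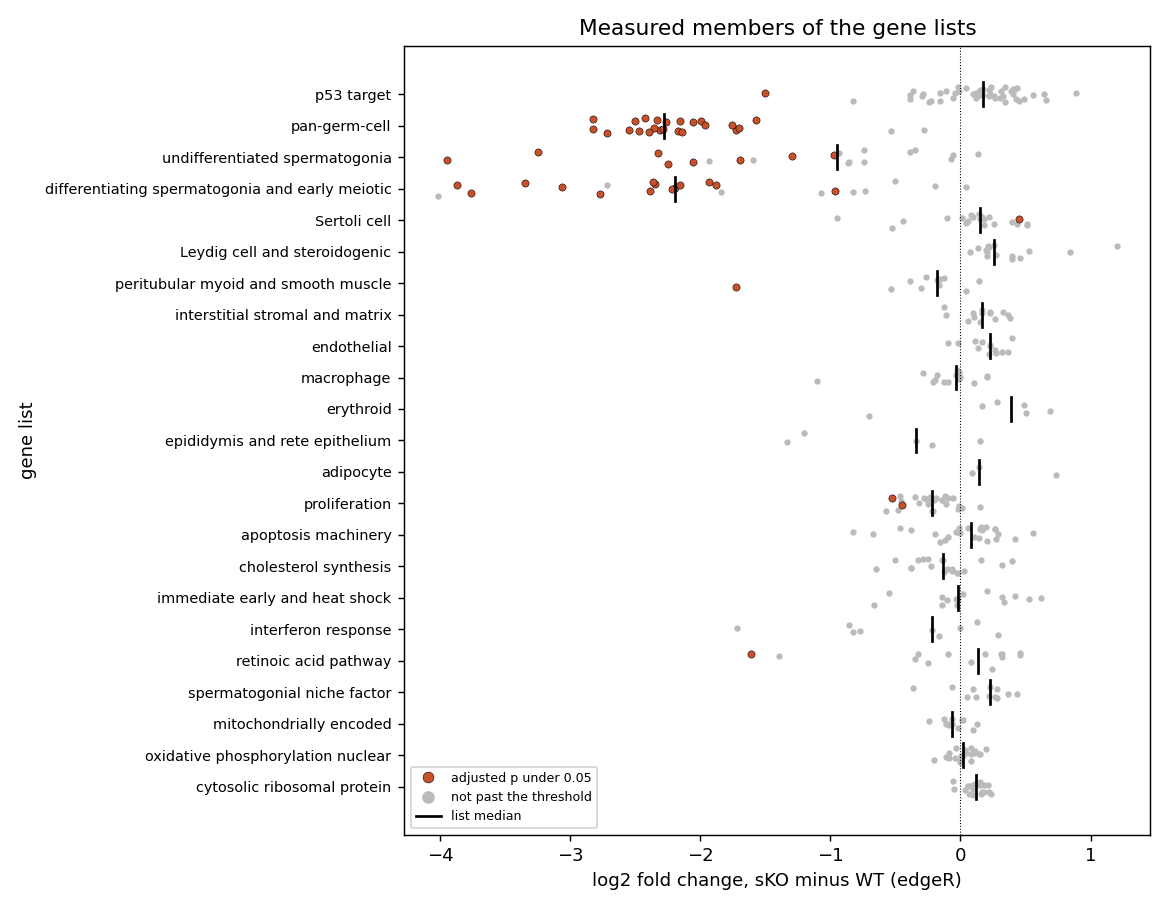
The log2 fold change of sKO over WT (x) of each measured member of the 23 gene lists (y), with orange points past adjusted p 0.05, grey points not past it and a bar for each list median. Medians were −2.28 for the pan-germ-cell, −2.20 for the differentiating and −0.95 for the undifferentiated list, and lay between −0.34 and 0.39 in the other lists.

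Genes of the somatic cells of the testis showed small shifts. Of 21 measured Sertoli cell genes, Amh, which encodes anti-Müllerian hormone, was the only one higher, from 345 ± 1.005 CPM (SD, n = 2) to 471 ± 22.9 (SD, n = 4; log2 fold change 0.45, SE 0.09, adjusted p = 0.0429), and 0 were lower. Adjusted over the list alone, 3 were higher and 1 lower. The Amh log2 fold change lost its call without WT-1 (adjusted p = 0.315), WT-2 (0.208), sKO-1 (0.0709), sKO-2 (0.124), sKO-3 (0.136) or sKO-4 (0.130), and with RLE factors (0.0538) or Sertoli library sizes (0.0904), which Amh itself helped to set. The transcription factor Sox9 was at 174 ± 9.43 and 175 ± 2.26 CPM (log2 fold change 0.01, adjusted p = 0.977). The Sertoli list had a median of 0.15 (0.26 and 0.06 within the subsets) and a camera adjusted p of 0.0409, with an adjusted p = 0.657 with an estimated correlation. Of 15 measured Leydig cell and steroidogenic genes 0 passed (median 0.26), and the steroid enzymes Hsd3b1 (0.26, SE 0.12) and Hsd17b3 (0.20, SE 0.15) were the most abundant. Of 14 stromal and matrix genes 0 passed (median 0.17), with the collagens Col3a1 at 0.15 (SE 0.16) and Col1a2 at 0.17 (SE 0.15), and of 13 endothelial genes 0 passed (median 0.22), with Cdh5 at 0.27 and Eng at 0.22. Camera gave adjusted p of 0.0121, 0.0409 and 0.0102 for the Leydig, stromal and endothelial lists, and adjusted p = 0.436, adjusted p = 0.702 and adjusted p = 0.347 with an estimated correlation. The Leydig median was 0.13 without WT-1 and 0.60 without WT-2. Without WT-1 the camera adjusted p was 0.838 for the Sertoli cell genes, 0.350 for the Leydig cell and steroidogenic genes, 0.851 for the interstitial stromal and matrix genes and 0.0757 for the endothelial genes. The Sertoli call also ended without sKO-2 (0.0511), sKO-3 (0.0994) or sKO-4 (0.0982), and the stromal call without sKO-3 (0.283) or sKO-4 (0.0982).

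Setting library size by the Sertoli genes moved the median of all genes by −0.15, which left the list medians at 0.11 for Leydig, 0.03 for stromal, 0.07 for endothelial and 0.08 for niche factor genes. The Sertoli median was 0.01 there, near 0 by construction. The medians that changed sign with it were those of the apoptosis machinery (−0.06), oxidative phosphorylation (−0.11), ribosomal protein (−0.02) and retinoic acid (−0.00283) genes. With the library subset as a term, 5 Sertoli genes were higher and 1 lower, and 2 Leydig, 6 stromal and 2 endothelial genes were higher and 0 lower. The stromal genes included the transcription factor Nr2f2 (0.39, adjusted p = 0.00415) and the receptor Pdgfra (0.36, 0.00424), named after their values were seen. Within the 2 subsets the medians were 0.43 and 0.17 for Leydig, 0.21 and 0.14 for stromal and 0.21 and 0.20 for endothelial genes.

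Of 11 measured peritubular myoid and smooth muscle genes, calponin, Cnn1, was lower, from 2.92 ± 0.169 CPM (SD, n = 2) to 0.878 ± 0.169 (SD, n = 4; log2 fold change −1.73, SE 0.30, adjusted p = 0.0323), and 0 were higher. Adjusted over the list alone 2 were lower, and 4 with the library subset as a term. The Cnn1 log2 fold change lost its call without WT-1 (adjusted p = 0.260), WT-2 (0.131), sKO-1 (0.0782), sKO-2 (0.0975), sKO-3 (0.0873) or sKO-4 (0.0546). The list median was −0.18, or −0.21 and −0.29 within the subsets (camera adjusted p = 0.0121, and adjusted p = 0.230 with an estimated correlation). Without WT-2 the peritubular myoid and smooth muscle genes lost their call (0.111). Of 16 macrophage genes 0 passed (median −0.03, camera adjusted p = 0.416), with Lyz2 at 0.20 and Mrc1 at −0.18. Of 12 niche factors that somatic cells supply to spermatogonia 0 passed over all genes and 1 was higher adjusted over the list alone. With the subset term 4 were higher, Kitl among them (adjusted p = 0.0266). The median was 0.22, with Kitl, the ligand of the Kit receptor, at 0.22 (SE 0.08) and Igf1 at 0.27 (SE 0.18), and camera gave an adjusted p of 0.0288, or an adjusted p = 0.257 with an estimated correlation. Without WT-1 (0.0757) or WT-2 (0.0837) the spermatogonial niche factor genes lost their call.

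Of 14 retinoic acid pathway genes, the retinol carrier Rbp4 was lower, from 2.80 ± 0.429 to 0.909 ± 0.201 CPM (−1.61, SE 0.32, adjusted p = 0.0464). Adjusted over the list alone 1 was higher and 2 were lower, and with the subset term 2 were higher and 2 lower. This list had a median of 0.14, a mean of −0.12 and a camera adjusted p of 0.836 pointing down. Leaving out any library ended the call of the Rbp4 log2 fold change (adjusted p 0.273 for WT-1, 0.206 for WT-2, 0.111 for sKO-1, 0.0869 for sKO-2, 0.130 for sKO-3 and 0.105 for sKO-4), and upper-quartile factors did so too (0.0529).

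In the remaining 9 lists 0 members passed over all genes. Adjusted over the list alone, 2 of 6 erythroid genes were higher, and 0 members of the other lists passed. With the library subset as a term, 7 cholesterol synthesis genes and 1 epididymis and rete gene were lower, and 4 ribosomal protein, 2 erythroid and 1 immediate early or heat shock gene were higher. The erythroid list, with Hbb-bs at 0.50 (SE 0.15) and Hba-a1 at 0.69 (SE 0.18), had a median of 0.39 and a camera adjusted p of 0.0479, or an adjusted p = 0.507 with an estimated correlation; reads of Hba-a1 can be shared with its near-identical copy, so its value is uncertain. Without WT-2 (0.326) or sKO-4 (0.0982) the erythroid genes lost their call, and within the subsets their median was 0.03 and 0.58. Epididymis and rete epithelium genes (5 measured) had a median of −0.34, with Epcam, an adhesion protein also made by germ cells, at −1.21 and Pax8 at −0.22 (camera adjusted p = 0.0993, and 0.0259 for the epididymis and rete epithelium genes without sKO-4, with an adjusted p = 0.528 with an estimated correlation and all 6 libraries). Their median ran from −0.77 without WT-2 to −0.14 without sKO-3. Adipocyte genes (3 measured), with Plin1 at 0.14 and Fabp4 at 0.73, had a camera adjusted p of 0.283. Cholesterol synthesis genes (20 measured), with Hmgcs1 at 0.32 and Srebf2 at −0.25, had a median of −0.13 (0.1002). Without WT-1 (0.00356), sKO-3 (0.0313) or sKO-4 (0.0269) the cholesterol synthesis genes passed the threshold, pointing down; with all 6 libraries and an estimated correlation the list had an adjusted p = 0.728. Their median was −0.32 without WT-1 and changed sign, to 0.05, without WT-2. Immediate early and heat shock genes (15 measured), with Egr1 at 0.33 and Jun at −0.03, had a median of −0.02, a mean of 0.05 and a camera adjusted p of 0.589 pointing up. Interferon response genes (9 measured), with Bst2 at −0.00380, had a median of −0.22 (0.1002).

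Of genes of energy metabolism and translation, the 13 mitochondrially encoded genes had a median of −0.07 (camera adjusted p = 0.459, and 0.0405 for the mitochondrially encoded genes without WT-1, with an adjusted p = 0.793 with an estimated correlation and all 6 libraries), with mt-Co1 at 0.02 and mt-Nd1 at 0.01. The 21 measured nuclear genes of oxidative phosphorylation had a median of 0.02 (0.599, and 0.0294 for the oxidative phosphorylation nuclear genes without WT-2, with an adjusted p = 0.873 with an estimated correlation and all 6 libraries), with the ATP synthase subunits Atp5b at 0.01 and Atp5a1 at 0.04. The 21 cytosolic ribosomal protein genes had a median of 0.12, with Rpl4 at 0.03 and Rpl3 at 0.16, and a camera adjusted p of 0.0121, or an adjusted p = 0.702 with an estimated correlation. Without WT-1 (0.824) or sKO-4 (0.0982) the cytosolic ribosomal protein genes lost their call.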

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

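In the 4 sKO libraries, the Dixon test compares the gap between the highest or lowest value and its neighbour with the whole range, and takes ratios above 0.829. It was applied to 94 named genes, list sums and library measures, and 4 were found. Chance alone gives 4.7 (about 1 in 20) if the 4 values of an item are independent draws from 1 normal distribution. The sKO libraries fell into pairs, so 4.7 is a rough guide. Pnmt was lowest in sKO-1, at 4.54 log2 CPM against 5.11 in the nearest library (ratio 0.838). Ccnb1 was highest in sKO-4, at 6.61 log2 CPM against 6.43 (ratio 0.951). The summed CPM of the Leydig cell and steroidogenic genes was lowest in sKO-1, at 10.3 on the log2 scale against 10.7 (ratio 0.837). The summed CPM of the erythroid genes was highest in sKO-4, at 9.47 against 8.995 (ratio 0.874).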

How the results depend on the processing

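The library subset term, the subsets alone, the libraries numbered 1 and 2 without the block, DESeq2 on the same filtered genes and the counts that were not rounded were chosen after seeing the data. None of the 35 named genes past the threshold changed direction under any alternative run. For the lists called by camera, the direction relative to the other genes was kept in the alternatives run, but their medians turned negative for ribosomal protein genes with Sertoli library sizes (−0.02) and, without WT-1, for Sertoli (−0.01) and stromal (−0.03) genes. Of all 67 named genes, 14 changed sign under at least 1 of 20 alternatives, and 5 lists not called by camera changed direction relative to the other genes, always short of the threshold. The cause of the changes below was not tested, except that leaving out libraries or raising the fold threshold removes data by construction. Leaving out WT-1 or WT-2 also leaves WT in 1 library subset. Those fits hold no subset term, so they mix the subset difference with genotype. With all 6 libraries and the subset term, camera gave adjusted p of 0.314 for mitochondrially encoded and 0.602 for oxidative phosphorylation genes. Genes higher in sKO numbered 22 of 17707 tested, and 81 with DESeq2 on 32531 genes without the count filter, 112 with DESeq2 on the same filtered genes, 30 in edgeR without the filter, 12 with Sertoli library sizes, 8 at a log2 fold change of at least 1, 880 with the library subset term, 312 in subset 1 alone, 126 in subset 2 alone and 1 to 7 with a library left out. Genes lower in sKO numbered 408, and 648 with DESeq2 without the count filter, 685 with DESeq2 on the same filtered genes, 541 in edgeR without the filter, 1531 with the subset term, 1028 in subset 1 alone and 1 to 221 with a library left out. The Mdm2 log2 fold change ran from −0.82 to −0.68 with a library left out. Only replicate numbers 1 and 2 occur in both groups, and the differences between them had a correlation across genes of −0.01 between the groups. This value cannot decide whether the numbers pair the libraries. WT-1 and WT-2 lie in different subsets, while sKO-1 and sKO-2 both lie in subset 1, so the subset split enters only the WT difference. The WT-1 minus WT-2 difference had a correlation of 0.57 with the difference between the sKO libraries of the 2 subsets. The subsets were taken from the same values, so this describes the split. Of the named genes past the threshold, 3 lost their call with RLE factors, 4 with upper-quartile factors, 3 with limma-voom, 7 with Sertoli library sizes and 12 with the block. With the replicate block in these 4 libraries, 19 genes were higher and 269 lower and the Mdm2 log2 fold change was −0.77; the same 4 libraries without the block gave 8, 171 and −0.76.

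With an estimated correlation the camera adjusted p was 0.348 for p53 target genes, 0.230 for pan-germ-cell genes, undifferentiated spermatogonia genes, differentiating spermatogonia and early meiotic genes and peritubular myoid and smooth muscle genes, 0.657 for Sertoli cell genes, 0.436 for Leydig cell and steroidogenic genes, 0.702 for interstitial stromal and matrix genes and cytosolic ribosomal protein genes, 0.347 for endothelial genes and proliferation genes, 0.507 for erythroid genes and 0.257 for spermatogonial niche factor genes. With fry, which asks whether a list's genes move 1 way on balance and compares them with no other genes, the adjusted p was 0.162 for p53 target, 0.360 for Sertoli, 0.278 for Leydig and erythroid, 0.518 for stromal, 0.0907 for endothelial, 0.0694 for proliferation and 0.387 for ribosomal genes. The fry adjusted p was 0.0115 for pan-germ-cell and differentiating, 0.0258 for undifferentiated, and 0.00718 for myoid and niche factor genes. RLE factors gave 0.0520 for erythroid genes, and Sertoli library sizes gave 0.0888 for Sertoli genes, which set those sizes, and 0.247 for ribosomal genes. The replicate block gave 0.447 for Sertoli, 0.955 for stromal, 0.171 for endothelial, 0.423 for erythroid, 0.169 for niche and 0.532 for ribosomal genes, and 7.40e-05 for cholesterol synthesis genes. The subset term gave 0.165 for erythroid and 0.00464 for cholesterol synthesis genes, whose adjusted p was 0.728 with an estimated correlation. The exact permutation test of the share of pan-germ-cell genes gave 0.0667, the smallest it allows.

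With a library left out, the adjusted p ran from 0.0269 to 0.116 for p53 target genes, 0.00231 to 0.838 for Sertoli cell genes, 8.02e-04 to 0.350 for Leydig cell and steroidogenic genes, 0.00917 to 0.111 for peritubular myoid and smooth muscle genes, 0.00154 to 0.851 for interstitial stromal and matrix genes, 0.00604 to 0.0757 for endothelial genes, 0.0242 to 0.326 for erythroid genes and 0.0259 to 0.348 for epididymis and rete epithelium genes. It ran from 0.00356 to 0.761 for cholesterol synthesis genes, 0.0233 to 0.0837 for spermatogonial niche factor genes, 0.0405 to 0.788 for mitochondrially encoded genes, 0.0294 to 0.889 for oxidative phosphorylation nuclear genes and 1.50e-04 to 0.824 for cytosolic ribosomal protein genes. With a library left out, list medians ran from −0.01 to 0.24 for Sertoli, −0.03 to 0.31 for stromal, 0.01 to 0.19 for ribosomal protein, −0.07 to 0.14 for oxidative phosphorylation, −0.17 to 0.03 for mitochondrially encoded, −0.35 to −0.11 for interferon response, −0.14 to 0.14 for retinoic acid, 0.21 to 0.55 for erythroid, 0.08 to 0.23 for adipocyte and −0.30 to −0.21 for myoid genes. At totals near 18.3 M counts, depth limits mainly genes of a few counts, such as Nanos2 at 0.452 CPM in WT and Dmrtb1 at 0.434 CPM in sKO.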

Other observations

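The genes and the tests of the germ cell share, of the deleted allele, of reads moving to a parent gene and of other splits of the libraries were chosen after their results were seen. Several further genes were lower in sKO testes past the edgeR threshold. Lin28b, a paralog of Lin28a that blocks let-7 maturation, was at 12.4 CPM in WT and 2.98 in sKO (log2 fold change −2.06, adjusted p = 0.00929), and Trim71 and Hmga1 were at −2.14 (0.0136) and −1.997 (0.00929). Heatr1 and Mdn1, which act in ribosome assembly, were at −1.20 (0.00929) and −1.22 (0.0110). The cell cycle genes Ccnd1 and Cdkn2a fell by 1.34 and 2.10 on the log2 scale (0.0152 and 0.0205), and the maintenance methyltransferase Dnmt1 fell by 0.52 (0.0328). Sdc2 (0.56, 0.0205), Egfr (0.46, 0.0464) and Serpina5 (0.44, 0.0441) were higher.

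The X chromosome held 66 of the 396 lower genes with a chromosome in GRCm38, or 16.7%, against 3.61% of the other tested genes (odds ratio 5.33, 95% interval 3.98 to 7.06, Fisher's exact test p = 6.84e-24; genes are not independent replicates). Of 23 tested genes on Y, 4 were lower. Mageb4 (−2.61, adjusted p = 0.0110) and Nxf2 (−2.66, 0.0110) were among the lower X-linked genes. So were members of the germ cell lists, such as Tex11 (−2.42), Taf7l (−2.51) and Usp26 (−2.36). The excess on X was not separated from the fall of germ cell transcripts. Some genes past the threshold had no count in 1 group. With a floor of 3 counts over the group, Gm15109 (121 counts in WT) was at least 80.6-fold lower and Gm37376 (66 counts) at least 44.0-fold lower in sKO, and Gm14339 (169 counts in sKO) was at least 28.2-fold higher; the limits cover counting error only.

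The libraries fell into a pair of subsets across genotype, with 6009 genes differing between them. The subsets were taken from the same values, so this number and the list tests between them describe the split and do not test it. From subset 1 to subset 2, 16 of 20 cholesterol synthesis genes and 12 of 14 stromal genes were higher (camera adjusted p 2.69e-06 and 3.72e-04), as were 9 ribosomal protein and 9 oxidative phosphorylation genes (9.31e-04 each) and 6 mitochondrially encoded genes (0.0290), each with an adjusted p = 0.951 with an estimated correlation. Smooth curves on GC content and on transcript length explained shares of 0.00231 and 0.00590 of the variance of the subset differences. These values argue against GC content and transcript length as the cause. The 20 most abundant genes held 7.58% of the counts in subset 1 and 8.40% in subset 2, a difference of 0.827 percentage points. The limit set for that difference was larger than either share, so it could not be passed and tested nothing. Their share was higher in every library of subset 2 than in any of subset 1. A dissection, litter or preparation day may underlie the subsets, but no label names one and no biological explanation was tested.

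The rise of Cpm, next to Mdm2, exceeded the largest log2 fold change among 90 somatic list genes (Mc2r, 1.2002) by 1.39, which argues against a lower share of germ cells as its whole cause. Of the 20 tested genes on each side of the pair, 1 was past the threshold, or 2.5% (95% upper limit 13.2%) against 2.43% of all genes, and with the subset term 20% (35.6%) against 13.6%, so a linked strain segment around Mdm2 stays open. The gain of Cpm exceeded the loss of Mdm2 by 5.73 CPM (SE 5.67). This comparison cannot decide, since reads gained at Cpm need not equal reads lost at Mdm2. The loss of Mdm2 may also include the fall of germ cell transcripts. Transcription or reads from the deleted Mdm2 allele cannot be told apart from a change at Cpm itself. The next tested genes beyond Cpm, Gm32365 (1 count in WT, 43 in sKO, adjusted p = 0.0855) and Kifc5c-ps (2 and 90, 0.0497), had log2 fold changes of 4.16 and 4.36. Kifc5c-ps was the 1 flank gene past the threshold. Both were among the 8 flank genes past it with the subset term (adjusted p 0.0295 and 0.00803), so the flank counts include genes that rose beside Cpm. On the other side, next to Mdm2, Slc35e3 (−0.13), Nup107 (−0.20) and Rap1b (0.04) did not pass in either fit.

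Gm12191 (2850 counts in WT, 37 in sKO) and Gm10184 (3419 and 72) had the log2 fold changes −7.22 and −6.52. The nearer, at its counting limit, lay 2.22 on the log2 scale below the lowest germ cell list gene. This argues against a lower share of germ cells as the whole cause only if germ cell genes fall no further than the list genes. Outside the lists, Gm15109 was at least 80.6-fold lower, against a limit of 75.3-fold for Gm10184, and whether it is a germ cell gene was not tested. The transcript of Gm15109 was not compared with others, so reads shared with a near-identical copy stay possible there too. Gm12191 and Gm10184 (2 of 2) had a near-identical parent, Rpl30 at 99.7% identity and Kpna2 at 99.9%, so their reads could be shared with it. Rpl30 was past the threshold upward (0.48, adjusted p = 0.0441), with a gain of 110 CPM against a loss of 76.7 for Gm12191, and Kpna2 was at 0.61 (0.156), with a gain of 41.8 against a loss of 90.6 for Gm10184. The sum of gene and parent changed by 0.13 (SE 0.12) for Gm12191 and −0.49 (SE 0.26) for Gm10184, so reads that moved to the parent gene cannot be told apart from a loss of expression, and a difference in strain background at these loci was not tested.

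Of the 15 splits of the libraries into 2 and 4, 1, the real one, gave as many as 430 genes past the threshold, and the highest other gave 8. The splits are too few for a share under 0.05.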
